A study of Mus musculus with 10 samples.

How the data were processed

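Small RNA profiles of exosomes from mouse serum were compared between mice infected with the malaria parasite *Plasmodium berghei* ANKA and uninfected mice. Exosomes are small membrane vesicles released by cells, and part of the miRNA of serum travels in them. There were 5 infected and 5 uninfected samples. Each was a pool of serum from 4 female C57BL/6 mice, which makes 20 mice per group, so the replicate is a pool and not an animal. Infected mice received 1000000 infected red cells into the peritoneum and were bled at 10 to 14 days, at about 40% parasitaemia. Uninfected mice received buffer and are labelled day 0, so that time after injection and infection cannot be told apart. The labels give no library batch.

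Reads were aligned to the mouse genome build mm10, with Novoalign 2.07.11 among the tools, per the submitters' processing notes. The rule for counting reads per miRNA, the scaling and the miRBase release are not given in the sources used here. The labels' protocols name an exosome precipitation kit, a column kit for RNA and a kit for messenger RNA libraries. Each deposited file lists 3059 lines, each a mature miRNA name and a value. The deposited values are treated as a score: they are whole numbers, but the 10 files sum to between 976696 and 989967, so the authors had brought each library close to a common total and rounded the result. They are therefore not read counts, and no count model was used. The depth of each library in reads is unknown. Every whole number from 1 to 27 occurs in every library, so 1 read is worth no more than about 1 unit, and the rounding hides the steps between reads. No counting interval or floor is given for this reason, and a blank in a file was read as 0.

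Names were used as deposited. Of 2931 distinct names, 1652 were known miRNAs and 1279 were predicted ones named by a chromosome. The files list 69 names on several lines, of which 23 have lines with differing values, and these lines were averaged. Mature sequences shared by paralogous hairpins cannot be assigned to one locus. Hairpin positions and host genes came from the GENCODE M21 annotation of the same build and are given 1-based.

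Values were transformed as log2(value + 1). Names with a value of at least 1 in at least 5 libraries were kept. Infected and uninfected pools were compared with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All fold changes are on this log2 scale, which understates the change of names with low values. Ratios of mean values are named as such. A plan for read counts had been written before the data were examined, with this limma fit as the fallback for normalized values. Lists of miRNAs were fixed at that time too. They were tested with camera (preset correlation of 0.01, and an estimated correlation) and fry, adjusted over the 15 lists. The lists held miRNAs of red cells, liver, innate immune signalling, myeloid cells, lymphocytes, endothelium and platelets, nervous tissue, muscle, and epithelia and pancreas. The others were the let-7 family, the miR-17-92 cluster with its paralogs, the miR-15/16 seed family, the imprinted Dlk1-Dio3 cluster, the Sfmbt2 intron cluster, and miRNAs named in earlier malaria work. The malaria list was drawn up from memory and not taken from a cited source. Members of the Sfmbt2 list were taken by the pattern of their names, without a check of their loci. For each of 155 hairpins with both arms tested, limma was run on the log2 ratio of the 5p to the 3p arm. Totals, numbers of names and shares per library were compared by exact two-sided permutation tests of the difference of means, adjusted over 8 measures, with scipy 1.17.1. The smallest p that 5 against 5 libraries allow is 0.00794.

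Named miRNAs followed a rule written before the data were examined. It took the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean of at least 50 and groups that did not overlap. It added the 10 most abundant names, up to 4 of the most abundant tested members of each list, and 8 fixed miRNAs. Names outside the rule are said to have been chosen after their values were seen.

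On simulated data 876 names were tested, some of them with known changes. The fit called 63.9% of 97 names changed by 1 log2 unit and 93.8% of 96 changed by 2 log2 units. Every call had the right direction and 0% of calls were false. Fewer of the simulated names were changed than the 57.3% called in the data, and no simulated pools stood apart within their group. The rate of false calls in the data is thus not measured by this. The list test recovered 1 of 1 changed lists with 0 false calls, and the arm test recovered 20 of 20 changed hairpins with 1 false call. Names were simulated independently and lists drawn at random, so members of a list were not correlated. In the data that correlation was estimated at 0.23 for the red cell list and 0.53 for the let-7 family. The rate of false list calls on such lists is therefore not measured. The simulated arm changes were larger than 2 log2 units. The alternatives tried were other filters, pseudocounts, scalings and treatments of repeated names, known miRNAs alone, a block on the replicate number, and the fit without each library in turn. The fit without infected pools 4 and 5, which stood apart from the other infected pools, was added after the data were seen. That fit kept names with a value of at least 1 in at least 4 libraries. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.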

Results

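Serum exosome miRNA values were compared in 5 pools from mice infected with *P. berghei* ANKA, a rodent malaria parasite that causes severe disease in C57BL/6 mice, and 5 pools from uninfected mice. The deposited values summed to between 976696 and 989967 per library, and read depth is unknown. Between 839 and 1060 distinct names had a value of at least 1 in a library, and 942 names were tested, 618 known and 324 predicted. The Spearman correlation across names ranged from 0.904 to 0.966 between infected pools, from 0.959 to 0.964 between uninfected pools and from 0.800 to 0.821 between pools of different groups. The first principal component held 67.4% of the variance and separated the groups. The second held 14.1%, with infected pools 1 to 3 at 11.4, 14.7 and 8.90 and infected pools 4 and 5 at -18.9 and -18.8.

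The main comparison asked which exosomal miRNAs differ with infection. miR-146a-5p, which is induced by innate immune receptors and dampens their signalling, rose from 5710 ± 487 to 61939 ± 12070 (SD, n = 5 pools per group), a 10.8-fold ratio of means. miR-21a-5p became the most abundant name in every infected pool, at 98262 ± 17476 against 37627 ± 2609 in uninfected pools, and miR-29a-3p rose from 13084 ± 991 to 65067 ± 10905. In the other direction, let-7i-5p fell from 69398 ± 4735 to 15355 ± 679, and miR-26a-5p fell from 18359 ± 1165 to 1526 ± 918. The red cell miRNA miR-486b-5p, the most abundant name in every uninfected pool, fell from 79096 ± 5005 to 53402 ± 10665.

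Of the 942 names, 540 changed at an adjusted p under 0.05 in the limma fit, 255 of them higher and 285 lower in infected pools. A change of at least 2-fold was seen for 430, with 204 higher and 226 lower, and for 265 with a pseudocount of 5. Among known miRNAs 146 were higher and 216 lower, and among predicted names 109 were higher and 69 lower. The groups did not overlap for 401 names, where chance gives 0.794% of names. Under the filter of at least 10 in at least 5 libraries, 318 of 470 names changed. Without infected pools 4 and 5, and with names kept at 1 or more in at least 4 libraries, 548 of 915 names changed. Of these, 428 changed by at least 2-fold. Among the 540 calls, 508 were tested in that fit and 464 were kept.

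The hairpins of the leading miRNAs lie at scattered loci of mm10. Mir146, the hairpin of miR-146a-5p, is on chromosome 11, 43374397 to 43374461 on the minus strand, with no host gene on its strand. Mir21a (miR-21a-5p) overlaps an annotated exon of Vmp1 on chromosome 11, 86584067 to 86584158, minus strand. Mir29a (miR-29a-3p) is on chromosome 6, 31062660 to 31062747, minus strand, with no host gene on its strand. Mirlet7i (let-7i-5p) overlaps an annotated exon of the pseudogene D630033A02Rik on chromosome 10, 122985640 to 122985724, minus strand. Mir511 (miR-511-3p) lies in an intron of Mrc1, the gene of the macrophage mannose receptor, on chromosome 2, 14261003 to 14261081, plus strand. miR-26a-5p is shared by Mir26a-1 and Mir26a-2. Mir26a-1 lies in an intron of Ctdspl on chromosome 9 (119031796 to 119031885, plus strand). Mir26a-2 overlaps an annotated exon of Ctdsp2 on chromosome 10 (126995530 to 126995613, plus strand). Exons of all annotated transcripts of a gene were considered, so a hairpin that overlaps one may be intronic in other transcripts.

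Among the 8 largest rises by the naming rule, miR-511-3p was the 1 known miRNA. It rose from 9.40 ± 2.19 to 151 ± 13 (log2 fold change 3.89 ± 0.17 SE, adjusted p = 6.91e-09, limma). The other 7 were predicted names. These are not printed by name here, and each is placed by the chromosome in its name. The one of chromosome 4 was blank, read as 0, in all 5 uninfected pools and averaged 366 ± 109 in infected pools. One of chromosome 6 averaged 320 ± 280 against 0.20 ± 0.45, and another of that chromosome 135 ± 135 against 0.40 ± 0.55, so that the infected pools varied widely for both. The one of chromosome 7 rose from 445 ± 62.9 to 5411 ± 2513, that of chromosome 2 from 39.2 ± 15.7 to 628 ± 390, that of chromosome 5 from 11 ± 2.83 to 211 ± 51.3 and that of chromosome 3 from 13.8 ± 4.82 to 161 ± 45.1. The largest falls were miR-199b-5p (log2 fold change -4.23 ± 0.53 SE), let-7c-5p (-3.96 ± 0.43), miR-26a-5p (-3.80 ± 0.34), let-7e-5p (-3.71 ± 0.32), a predicted name of chromosome 18 (-3.35 ± 0.42), miR-98-5p (-3.15 ± 0.37), miR-486a-3p (-3.11 ± 0.25) and miR-374b-5p (-2.93 ± 0.55). All 8 had an adjusted p of 0.00062 or lower in the limma fit. Without infected pools 4 and 5 all 8 passed and were deeper, at -5.17 for miR-199b-5p, -4.77 for let-7c-5p, -4.42 for miR-26a-5p, -4.26 for let-7e-5p, -3.95 for miR-374b-5p, -3.85 for the name of chromosome 18, -3.82 for miR-98-5p and -3.47 for miR-486a-3p. The order thus changed, with miR-374b-5p moving ahead of the name of chromosome 18, miR-98-5p and miR-486a-3p. The 2 rises of chromosome 6 also changed places, from log2 fold changes of 7.75 and 5.44 to 7.02 and 7.30. That of chromosome 2 (3.76 to 4.35) moved ahead of that of chromosome 5 (4.15 to 4.07) and of miR-511-3p (3.89 to 3.94). That of chromosome 7 (3.46 to 4.02) also moved ahead of miR-511-3p. The name of chromosome 4 was not tested in that fit. Of the 10 most abundant names, miR-142a-5p at 33576 ± 5529 against 33229 ± 3542 and miR-140-3p at 33784 ± 9484 against 30552 ± 1536 did not pass the test.

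**Figure D1:**
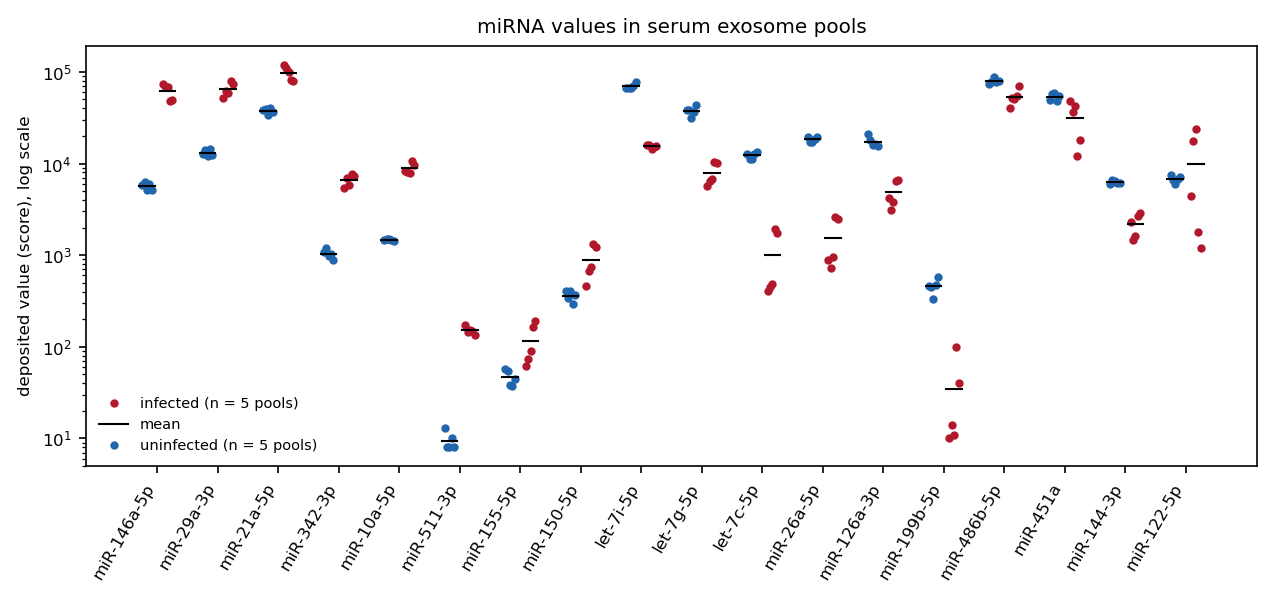
Deposited values (scaled by the authors to a common total, log axis) of 18 miRNAs in each pool, with infected pools in red, uninfected pools in blue and group means as black bars. miR-146a-5p averages 61939 in infected and 5710 in uninfected pools, whereas miR-122-5p ranges from 1192 to 24050 among infected pools and overlaps the uninfected ones.

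The lists of miRNAs fixed beforehand asked whether miRNAs of one cell type, family or cluster moved together. The let-7 family, which restrains growth genes and is abundant in blood, fell: 9 of 10 tested members were lower and none higher, with a median log2 fold change of -2.73. let-7g-5p fell from 37636 ± 4294 to 7892 ± 2235, let-7d-5p from 15638 ± 565 to 2500 ± 1383 and let-7f-5p from 14718 ± 939 to 2648 ± 1473. The exception, chosen after its values were seen, was let-7k, at 30.8 ± 8.64 in infected and 29.4 ± 5.41 in uninfected pools. The same 9 were lower when adjusted over the list alone. Without infected pools 4 and 5 the median log2 fold change of the family was -3.28. The camera test gave an adjusted p of 0.000176 with the preset correlation, and adjusted p = 0.456 with an estimated correlation. The share of each library taken by the family was 3.51 ± 0.79% in infected and 18.6 ± 1.19% in uninfected pools (exact permutation p = 0.00794, adjusted p = 0.0159), lower in 5 of 5 infected pools than in any uninfected pool.

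The red cell list also fell, with 9 of 12 tested members lower, 1 higher and 2 not called, and the same counts when adjusted over the list alone. miR-486a-5p, whose hairpin lies in an intron of the erythroid ankyrin gene Ank1, fell from 70411 ± 4655 to 50414 ± 9688, miR-25-3p from 37711 ± 3439 to 20294 ± 2416 and miR-16-5p from 2489 ± 241 to 1331 ± 103. Chosen after their values were seen, miR-144-3p fell from 6272 ± 280 to 2201 ± 634 and miR-144-5p from 1525 ± 236 to 250 ± 135, while miR-363-3p rose from 112 ± 6.44 to 370 ± 82.5. The list had an adjusted p of 0.0145 in camera, and adjusted p = 0.456 with an estimated correlation. Its share was 17.9 ± 1.49% in infected and 28.8 ± 1.94% in uninfected pools (exact permutation p = 0.00794, adjusted p = 0.0159). The difference of -10.9 percentage points was -6.73 without the names above 5% mean share, among them miR-486a-5p and miR-486b-5p of this list. The values of these names ran closely in parallel, from 37577 and 40538 in infected pool 1 to 78120 and 87039 in uninfected pool 3. They may not be independent members, although the counts and the share include both. miR-451a, a red cell miRNA matured without Dicer, had 31424 ± 15712 against 53365 ± 4887 and a log2 fold change of -0.94 ± 0.33 SE (adjusted p = 0.0289, limma), with overlapping groups. Its call was lost without infected pool 5 (-0.79, adjusted p = 0.0595), uninfected pool 2 (-0.92, 0.0529), uninfected pool 3 (-0.91, 0.0572) or uninfected pool 5 (-0.93, 0.0509). It was also lost with median-of-ratios scaling (-0.84, adjusted p = 0.0555) and with no filter on low values, where its fold change stayed at -0.94 (adjusted p = 0.082), and over all alternatives its adjusted p ranged from 0.00975 to 0.082. Its log2 fold change was smaller, at -0.34, without infected pools 4 and 5, where the call was kept (adjusted p = 0.0138, limma). The log2 ratio of miR-451a to miR-23a-3p, a usual index of haemolysis, was -0.93 ± 0.92 in infected and 0.62 ± 0.25 in uninfected pools (exact permutation p = 0.00794, adjusted p = 0.0159), and was -2.10 and -1.72 in infected pools 4 and 5. The reference miR-23a-3p itself rose from 34764 ± 3038 to 52671 ± 3814 (log2 fold change 0.60 ± 0.10 SE, adjusted p = 0.000259, limma). Part of the difference in the ratio thus comes from the reference, and the ratio is no clean measure of haemolysis here.

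The innate immune list rose, with 9 of 13 members higher, 1 lower and 3 not called, and the same counts when adjusted over the list alone. Beside miR-146a-5p and miR-21a-5p, miR-221-3p rose from 4533 ± 631 to 10577 ± 1304 and miR-146b-5p from 311 ± 22.5 to 600 ± 204. miR-155-5p, induced in activated macrophages and lymphocytes, rose from 46.4 ± 9.32 to 116 ± 58.4, with infected pools 4 and 5 highest. Its log2 fold change was 1.18, and 0.68 without those pools (adjusted p = 0.00755, limma). miR-147-3p and miR-21a-3p, chosen after their values were seen, rose from 18.6 ± 4.56 to 183 ± 68.5 and from 30.0 ± 4.30 to 312 ± 28.0. The list had an adjusted p of 0.00676 in camera, and adjusted p = 0.456 with an estimated correlation.

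The lymphocyte list rose as well, with 7 of 11 members higher, 2 lower and 2 not called, the same counts when adjusted over the list alone. miR-342-3p, from an intron of Evl, rose from 1029 ± 108 to 6624 ± 948, and miR-150-5p, a miRNA of mature lymphocytes, from 361 ± 49.4 to 882 ± 366. miR-181a-5p was at 2112 ± 642 against 1587 ± 166 and did not pass the test. Part of this list is not specific to lymphocytes: miR-29a-3p and miR-29c-3p occur in many tissues, and miR-155-5p stands in the innate list too. miR-29c-3p and miR-29b-3p, chosen after their values were seen, rose by 3.43 and 2.96 log2 units. The list had an adjusted p of 0.0146 in camera, and adjusted p = 0.472 with an estimated correlation. Without infected pools 4 and 5 its median log2 fold change was 0.68 instead of 1.18 (adjusted p = 0.0141 in camera), and that of miR-150-5p 0.77 instead of 1.19.

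Both imprinted or tandem clusters fell. In the Dlk1-Dio3 cluster, expressed from the maternal chromosome, 28 of 40 tested members were lower, 1 higher and 11 not called, with a median log2 fold change of -1.14. miR-434-3p fell from 940 ± 152 to 263 ± 168, miR-379-5p from 573 ± 93.1 to 182 ± 13 and miR-127-3p from 334 ± 109 to 104 ± 22.3. In the list of the Sfmbt2 intron cluster, drawn up by name pattern, 15 of 23 tested members were lower and none higher, at low values. Some members have identical values in all pools, so that the 23 are 19 distinct profiles and the 15 are 12. With names of identical values counted once, the list had an adjusted p of 0.00616 in camera. miR-467e-5p fell from 21.4 ± 5.64 to 2.60 ± 1.95 and miR-467c-5p from 19 ± 1.0 to 3.20 ± 1.92. Counts adjusted over the list alone were the same for both. The adjusted p in camera was 0.000141 for Dlk1-Dio3 and 0.000225 for Sfmbt2, and adjusted p = 0.273 with an estimated correlation for each. Under the filter of at least 10 in at least 5 libraries the Sfmbt2 list had 3 members left and no longer passed (adjusted p = 0.202), with a median log2 fold change of -2.38 instead of -1.0. Its median was -0.45 with a pseudocount of 5 and -0.46 with no filter on low values, and the list passed in both.

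The other 9 lists did not pass in camera. The fry test, which asks whether a list's members move one way on balance and compares it with no other list, gave an adjusted p of 2.75e-05 or lower for the 6 lists above. It also passed for 5 of the 9: endothelium and platelets (0.00247), miR-15/16 (0.00521), epithelia and pancreas (0.010), muscle and miR-17-92 (0.0208 each). Liver miRNAs had 1 of 6 tested members lower, and miR-122-5p, the main miRNA of hepatocytes, was at 9819 ± 10413 in infected and 6796 ± 584 in uninfected pools, a log2 fold change of -0.37 ± 0.72 SE whose sign differs from that of the means. The liver values turned on infected pools 4 and 5: without them the list's median log2 fold change was 0.996 instead of -0.03 (adjusted p = 0.251 in camera) and that of miR-122-5p 0.86 (adjusted p = 0.162, limma). miR-192-5p and miR-194-5p, not called with all pools, then passed as higher, by 1.13 and 1.39. The myeloid list had 3 higher and 2 lower of 10, with miR-23a-3p, miR-27a-3p and miR-24-3p higher and miR-223-3p at 147 ± 55.5 against 161 ± 8.51. Its median log2 fold change was 0.14 and its mean -0.07. The list of endothelium and platelets had 5 higher and 4 lower of 12: miR-10a-5p rose from 1474 ± 34.6 to 8942 ± 1237 and miR-22-3p from 9776 ± 1518 to 23119 ± 4268, whereas miR-126a-3p, the main endothelial miRNA, fell from 17370 ± 2202 to 4833 ± 1614. Its median was -0.04 and its mean 0.20. In the muscle list 4 of 7 were lower and 1 higher, and miR-206-3p fell from 4152 ± 1409 to 1490 ± 66.6 and miR-133a-3p from 6512 ± 1604 to 2578 ± 404. miR-1a-3p, abundant in heart and skeletal muscle, was not called (0.20 ± 0.50 SE), but passed as higher without infected pools 4 and 5 (1.08, adjusted p = 0.00114, limma). Neural miRNAs had 1 higher and 3 lower of 12 (2 lower when adjusted over the list alone), with miR-128-3p lower and miR-132-3p at 97.6 ± 45.0 against 101 ± 10.7. Epithelial and pancreatic miRNAs had 8 higher and 4 lower of 14, among them miR-205-5p, which rose from 247 ± 31.4 to 1262 ± 370. The miR-17-92 list had 5 higher and 2 lower of 14, and the miR-15/16 seed list 3 higher and 2 lower of 8 (median -0.09, mean 0.50). The list recalled from earlier malaria work had 8 higher and 7 lower of 19. The median of the miR-15/16 list was -0.42 without infected pools 4 and 5 and ranged from -0.68 to 0.02 over the alternatives. miR-15b-5p, not called with all pools (-0.45), passed as lower without infected pool 5 (-0.68) and without pools 4 and 5 (-1.01). For these lists, the neural one aside, the counts adjusted over the list alone were the same.

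**Figure D2:**
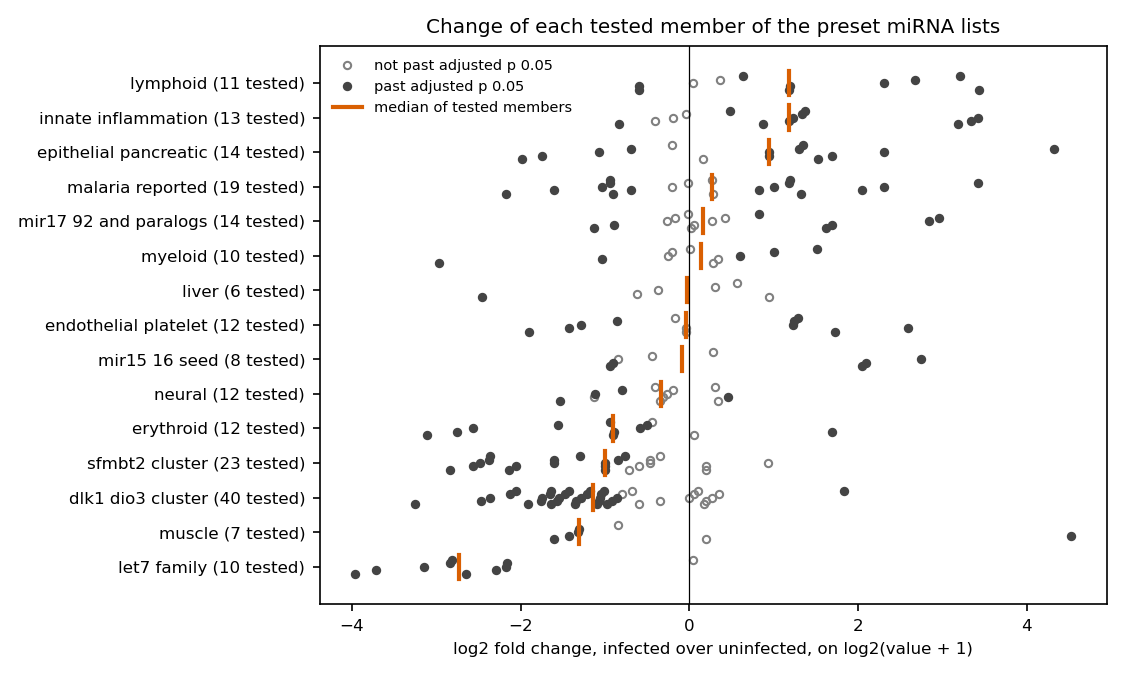
Log2 fold change (infected over uninfected) of each tested member of the 15 lists, filled where the adjusted p is under 0.05, with the median of each list as an orange bar. The let-7 family lies lowest, with a median of -2.73, and the innate immune and lymphocyte lists have medians of 1.18.

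A further comparison asked whether the 2 arms of a hairpin moved together. The arms changed apart in 95 of 155 hairpins at an adjusted p under 0.05 (limma on the ratio of the arms), with the 5p arm lower relative to the 3p arm in 56 and higher in 39. Of the hairpins, 91 had fold changes of the same sign in both arms, 16 had both arms higher, 21 both lower, and 16 had arms called in opposite directions. All 6 tested hairpins of the let-7 family were among those apart: their 5p arms fell by 2.88 to 4.56 log2 units relative to the 3p arms (negative ratios). The let-7 3p arms and the hairpins of miR-21a and miR-10a were picked for mention after their values were seen. The 3p arms of let-7b, let-7g and let-7i were called higher, and none was called lower. let-7i-3p averaged 124 over all 10 pools and let-7i-5p 42376, whereas let-7d-3p averaged 1531 and let-7d-5p 9069. miR-21a had both arms higher, with log2 fold changes of 1.37 for 5p and 3.34 for 3p, and miR-10a moved alike in both arms, by 2.59 and 2.62. With at least 10 in at least 5 libraries, 57 of 79 hairpins had arms apart. Without infected pools 4 and 5, and with names kept in at least 4 libraries, it was 99 of 157.

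**Figure D3:**
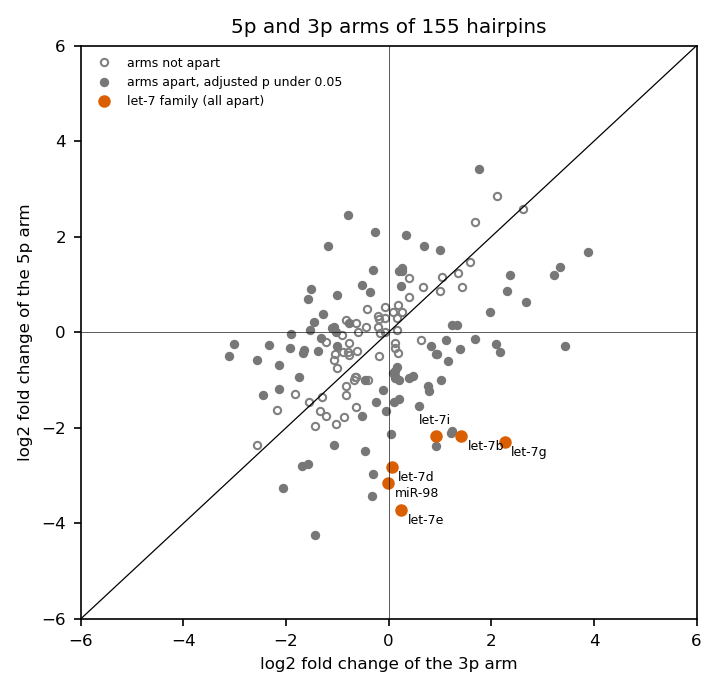
Log2 fold change of the 5p arm (vertical axis) against that of the 3p arm (horizontal axis) for 155 hairpins, with the line of equal change. The 6 let-7 family hairpins, in orange, lie far below the line, and let-7i has -2.17 for the 5p arm and 0.92 for the 3p arm.

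The number of names at 1 or more was 954 ± 88.4 in infected and 939 ± 102 in uninfected pools (exact permutation p = 0.817, adjusted p = 0.817), and the number at 10 or more 447 ± 22.0 and 459 ± 18.4 (exact permutation p = 0.341, adjusted p = 0.390). The most abundant name took 10.4 ± 1.81% and 8.75 ± 0.55%, and the 10 most abundant 55.1 ± 1.18% and 53.7 ± 1.37% (exact permutation p = 0.103 for each, adjusted p = 0.138). The total over distinct names was 941699 ± 6422 and 904015 ± 4125 (exact permutation p = 0.00794, adjusted p = 0.0159). Its direction depends on averaging names that stand on several lines: with those lines summed the difference was -6801 instead of 37684, and infected pools were then lower (adjusted p = 0.0127, exact permutation).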

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

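Among 211 sets of 5 pools examined for a pool far from its group, 8 had one, where chance gives about 1 in 20, or 10.6. The measure was the gap to the nearest pool as a share of the group's range. It can miss 2 pools that stand apart together, as infected pools 4 and 5 did on the second principal component. The number flagged therefore does not show that the pools of a group agree. In uninfected pool 5, let-7i-5p was at 77587, against 66397 to 69375 in the other uninfected pools. In uninfected pool 1, miR-206-3p was at 6565, against 3045 to 3997, and miR-127-3p at 519, against 246 to 323. In uninfected pool 2, miR-142a-3p was at 1643, against 1348 to 1414, and a predicted name of chromosome 6 at 1, where it was blank in the other 4. miR-15a-5p was at 185 in uninfected pool 5, against 207 to 215. miR-146b-5p was at 272 in uninfected pool 3, against 316 to 326. miR-429-3p was at 52 in infected pool 5, against 70 to 76 in the other infected pools.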

How the results depend on the processing

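Median-of-ratios and quantile scaling, known miRNAs alone, other treatments of repeated names and the fit without infected pools 4 and 5 were chosen after the data were seen. Among the 540 calls, none reversed in any alternative fit in which its name was tested: 316 were tested with at least 10 in at least 5 libraries, 362 with known miRNAs alone, 488 with median-of-ratios scaling, and 504 to 512 without each library in turn. With at least 10 in at least 5 libraries, 318 names changed, 238 by at least 2-fold, and 57 hairpins had arms apart, out of fewer tested. A pseudocount of 5 left 265 names at 2-fold or more, and known miRNAs alone gave 274. Without each library in turn, 475 to 501 names changed, 393 to 401 by 2-fold, 6 lists passed each time, and 78 to 93 hairpins had arms apart. Median-of-ratios scaling moved the shared median by 0.10 and gave 50.4% higher calls against 47.2%. Of 2139 values of named miRNAs under the alternatives, 16 lost and 10 gained a call. miR-132-3p reversed to 0.35 (adjusted p = 0.0469) without infected pools 4 and 5; the cause was not tested. Of 330 list values, all from camera with the preset correlation of 0.01, 1 lost its call. With an estimated correlation none of the 6 lists passed in the main fit (adjusted p of 0.273 to 0.472, camera). Read depth is unknown, and rounding to whole units limits names of low value most.

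Without infected pools 4 and 5, the differences in the total (41928), the miR-451a ratio (-0.89), the red cell share (-11.0) and the let-7 share (-15.6) had adjusted p = 0.0571, with only 3 against 5 pools left. With lines of repeated names summed, the total reversed to -6801 (adjusted p = 0.0127) and the share of the 10 most abundant names passed the test, at 3.21. Without each library in turn, the difference in the total was 36044 to 40101, in the miR-451a ratio -1.75 to -1.25, in the red cell share -11.4 to -10.1 and in the let-7 share -15.3 to -14.5. The names at 1 or more differed by -9.55 to 45.7.

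The replicate numbers do not pair the pools: pools with the same number had correlated deviations of -0.08 to -0.02, and none matched its own number best. A block on the number gave 514 calls, 506 of them among the 540, 425 at 2-fold or more, 6 lists and 90 hairpins. Sign flips within 5 pairs cannot give a p under 0.0625, so the block left the total (37684), the miR-451a ratio (-1.54), the red cell share (-10.9) and the let-7 share (-15.0) at adjusted p = 0.125. Alternatives planned for read counts (other count models and scalings, and thinning) were not run, because the values are not counts.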

Other observations

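The test of names present only in infected pools, the Fisher tests and the test of the spread of red cell miRNAs were chosen after their results were seen, and the other tests of explanations were set down after the patterns were noticed but before those tests were run. Muscle and epithelial lists held members that moved against the rest. miR-208a-3p, encoded in an intron of the cardiac myosin gene Myh6 on chromosome 14, was at 32.6 ± 7.60 in infected and 0.60 ± 0.89 in uninfected pools, while miR-499-5p, also of heart and slow muscle, fell from 298 ± 43.9 to 99.6 ± 28.8 (n = 5 pools per group). miR-217-5p, a pancreatic miRNA, rose from 3.40 ± 1.52 to 84.6 ± 26.6, while miR-200c-3p fell from 165 ± 16.1 to 41.6 ± 9.94 and miR-429-3p from 236 ± 31.8 to 69.4 ± 10.0. In the miR-17-92 list the paralogs of chromosome X moved most: miR-106a-5p rose from 19.2 ± 2.59 to 165 ± 65.7 and miR-20b-5p from 34.4 ± 5.68 to 264 ± 89.7. miR-99a-5p fell from 7103 ± 570 to 2960 ± 625, while miR-99b-5p rose from 834 ± 41.6 to 2889 ± 1021. All of these were chosen after their values were seen.

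A chance division of the pools can be excluded at the 5% level for the counts of changed names and of hairpins. This cannot tell infection from time after injection or from a library batch shared by a whole group. Of 100 splits of the 10 pools into 5 and 5, 1, the real one, gave as many as 540 changed names, and the highest other gave 0. For 2-fold changes (430) and hairpins with arms apart (95) it was likewise 1 of 100, with a highest other of 0. Every other split mixes infected and uninfected pools, so these values of 0 do not measure the rate of false calls. For lists it was 4 of 100, under 5%, but the highest other split also gave 6, so the number of lists past camera is weak evidence. Most other splits had at least 1 list past camera at the preset correlation, although none had a changed name. The adjusted p of a single list from that test is therefore weak evidence too.

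The fall of the let-7 family may reflect infection, as a hypothesis, and 3 technical explanations were examined. If scaling to a fixed total were the cause, the median of its members should rise to near 0 with median-of-ratios scaling, but it was -2.62, and -2.86 to -2.47 without each pool in turn. That scaling is itself relative, so this shows a fall against the typical name and not in absolute amount. The 9 of 10 members with a hairpin GC value, which leave out let-7k, the member not called, lay -2.89 log2 units from the 50 known miRNAs nearest to their median GC, whose median was 0.08. Only the GC of the hairpin was matched and not that of the mature miRNA, so a GC bias of the libraries stays open. Reads moved between paralogs would leave the family sum in place, but its log2 value differed by -2.37 (exact permutation p = 0.00794). With 9 of 10 members lower the sum could hardly stay in place, so it adds little to the values of the members. Time after injection, labelled day 0 for uninfected and 10 to 14 days for infected pools, stays open, as does any library batch.

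The red cell list also fell with median-of-ratios scaling, where its median was -0.79, and -0.87 to -0.63 without each pool in turn. miR-451a by itself lost its call under that scaling (-0.84, adjusted p = 0.0555, range over its alternatives 0.00975 to 0.082). The list thus fell relative to the typical name. Because that scaling is itself relative, it cannot tell a loss of red cell miRNAs from a gain of most others. The log2 fold changes of the list's members had an SD of 1.33 against a largest SE of 0.33. The arms of miR-486a moved apart by 2.61 ± 0.25 SE (adjusted p = 2.37e-06, limma). This spread cannot decide whether more lysed red cells in the uninfected serum were the whole cause. Lysis would move the members alike only if each came from red cells in the same proportion, which is unknown. Whether lysis caused the fall or a part of it stays open. The test set beforehand, the group difference of log2(miR-451a / miR-144-3p), was 0.62 (exact permutation p = 0.230), past its bound of 0.5 in size but not in p. Its condition counted a missed p in favour of lysis, but a missed p does not show that values agree, so it is read here as undecided.

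Predicted names took more of the infected libraries: they summed to 48768 ± 5082 against 18024 ± 2003, a ratio of 2.71 (exact permutation p = 0.00794). A predicted name of chromosome 8 matched the known miR-24-3p within 5% in all pools, and without it the ratio was 2.67. Without the 5 most abundant predicted names it was 1.77: these 5 names carried 68.1% of the rise, but not all of it, and a predicted name of chromosome 13 alone, chosen after its values were seen, rose from 1282 ± 190 to 8040 ± 1843. Names listed in all 5 infected and no uninfected pools numbered 19 of 324 predicted and 9 of 618 known (Fisher exact p = 0.000354), against 5 and 18 listed in all 5 uninfected and no infected pools (Fisher exact p = 0.267), but the 19 predicted names carried 2.06% of the rise, so RNA present only in infected pools does not account for most of it. Whether any of these names derive from parasite RNA was not tested.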
